A study of Homo sapiens with 9 samples.

How the data were processed

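Alveolar type 2-like cells carrying surfactant protein C (SFTPC) were obtained, per the labels, from organoids of the B2-3 human induced pluripotent stem cell line grown with human fetal lung fibroblasts. The organoids had been passaged 3 times, every 2 weeks, and were then exposed for 10 days to 5 µM GNE7915, an inhibitor of the kinase LRRK2, to 10 µM amiodarone, a cationic amphiphilic antiarrhythmic drug, or to vehicle (DMSO). SFTPC-positive cells were isolated on day 77, and total RNA was labelled with Cy3 and hybridised to Agilent expression arrays. Each of the 3 groups held 3 arrays, which the labels call biological replicates, so that 9 arrays were analysed, and no array was left out.

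The deposited scanner files of the authors hold a background-subtracted signal intensity for each spot on a linear scale, with no scaling between arrays, together with raw median spot and background intensities and flags per spot. Per the file headers, 2 of the arrays (vehicle replicate 1 and GNE7915 replicate 1) were extracted with Agilent Feature Extraction 11.5.1.1 and the other arrays with 12.0.3.1. The arrays were scanned on 4 dates, which coincide with 4 slides. Vehicle replicate 1 was alone on date 1 and GNE7915 replicate 1 alone on date 2. Date 3 held vehicle replicates 2 and 3, GNE7915 replicates 2 and 3 and amiodarone replicate 1, and date 4 held amiodarone replicates 2 and 3. Only date 3 therefore held more than 1 group. The deposited value table of the authors gives log2 values, which were checked against the scanner files. For each array they followed the logarithm of the scanner signal with a slope between 0.9998 and 1.0001, after each probe had been centred on the mean of the 3 vehicle arrays. The medians of its columns lay between -0.11 and 0.10.

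Each array carried 62976 spots, of which 4259 were controls. Control spots were left out, as were the 3409 of 528453 other spots (9 arrays together) that carried an outlier flag. No spot was saturated (0 over all arrays). Spots of 1 probe were averaged, which left 50599 probes, and 107 probes of the Y chromosome or of X inactivation were left out to protect privacy. Probe names were matched by accession to the gene table supplied (assembly GRCh38.p14), which named 30275 probes (59.8%). The probes were designed on another build, so no coordinates are given. The signal was put on the log2 scale, and the 75th percentile of the non-control probes of the array was subtracted from it. A probe was kept when it was well above background on at least 3 of the 9 arrays, and each gene was represented by its brightest probe. This gave 22976 genes for testing, 16200 with an approved symbol and 6776 known by another name, and 4593 of them had several probes. Between 56.33% and 60.59% of probes were well above background on an array, the 75th percentile of the signal lay between 306.79 and 394.08, and the median background between 23 and 32. With 3 arrays per group, the number of arrays limits the precision, and the median standard error (SE) of a log2 fold change was 0.20.

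Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in a single fit of the 3 groups, with 6 residual and 2.17 prior degrees of freedom. Benjamini-Hochberg adjustment was made over all genes tested and the threshold was an adjusted p of 0.05. Group values are means of the scaled log2 signal with the standard deviation (SD). Intervals are 95% intervals of the same fit. Where no array of a group was well above background, the fold is given as a lower bound, computed with that group raised to the dimmest signal that Feature Extraction called well above background on the array. The comparisons were GNE7915 against vehicle, amiodarone against vehicle, and amiodarone against GNE7915. The overlap of the calls of both drugs was compared with simulated data in which no gene was changed by either drug and both were compared with the same vehicle arrays.

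A total of 34 gene lists, 702 genes, was fixed before the data were examined. They covered surfactant and lamellar body genes, lung epithelial regulators, lipid metabolism, lysosome and autophagy, LRRK2 and its partners, stress and signalling responses, and markers of the other cell types that the organoids or the sort could hold. Of the list genes, 633 were tested. CPM, SFTA3 and a few others had no matched probe and were not analysed here. Lists were tested with camera of limma (preset inter-gene correlation 0.01, Benjamini-Hochberg over the 34 lists), again with a correlation estimated for each list, and with fry. Camera asks whether the genes of a list ranked higher or lower than the other genes, and fry whether they moved on balance in 1 direction. Members were also counted after adjustment over all genes and over the list alone.

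The genes named were set by a rule, also fixed before the data were examined. In each comparison with vehicle these were the 10 largest rises and the 10 largest falls past the threshold, among genes with an approved symbol whose 3 treated arrays all lay on 1 side of the vehicle arrays. Where no gene passed in a direction, the 5 with the smallest p were given as values. For amiodarone against GNE7915 the number was 5 in each direction. Up to 4 members with the smallest p were named for each list described (surfactant and lamellar body, cholesterol, phospholipids, lysosomal hydrolases, LRRK2 and its partners, and every list that passed), and SFTPC, LRRK2, SFTPB, SFTPA1, SFTPA2, SFTPD, ABCA3, LAMP3, NAPSA, NKX2-1, LPCAT1 and CPM were always to be named. A few genes that the rule names are not reported.

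The labels state no pairing. Same-numbered vehicle and GNE7915 arrays deviated from their group means together (Pearson correlations across genes of 0.41, 0.34 and 0.30), and differently numbered ones did not (-0.271 to -0.05). Genes are not independent replicates. Amiodarone replicate 1 deviated as strongly with GNE7915 replicate 3 (0.413) and vehicle replicate 3 (0.395), so such a value does not by itself mark a pair. The results of GNE7915 against vehicle are also given with the replicate number as a block, fitted to the vehicle and GNE7915 arrays alone. For the lists this block was also fitted with an estimated correlation. Scan date was fitted as a fixed block, and since only date 3 holds more than 1 group, the estimates of this fit are those within date 3. These fits, a random block for scan date, the 5 arrays of date 3 alone and the 7 arrays of the later software alone were added after the data had been seen, except that scan date and the replicate number as blocks in the fit of all arrays had been planned for the counts of genes.

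Alternatives planned beforehand were quantile normalization, median scaling, normexp background correction (offset 50), the value table of the authors, no filter on dim probes or a filter on all 9 arrays, the mean of the probes of a gene or every probe alone, outlier spots kept, only the 2 groups compared, array weights, a mean-variance trend, a 2-fold minimum, and each array left out in turn. The files hold no mean signal per spot, so that the raw median signal was used for normexp.

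The fit was tested on simulated data with the group sizes and the spread of these arrays (22976 genes). For GNE7915 against vehicle it called 30% of genes changed 2-fold, 78% of those changed 4-fold, 90% of those changed 8-fold and 92% of those changed 16-fold, with 8 false calls. For amiodarone against vehicle the shares were 48%, 78%, 82% and 98%, with 10 false calls, and for amiodarone against GNE7915 they were 46%, 85%, 93% and 96%, with 13 false calls. In the simulation of GNE7915 against vehicle, camera with the preset correlation gave an unadjusted p under 0.05 for 3 of 100 unchanged lists. Genes were drawn independently of each other in these simulations. They therefore do not test how the preset correlation serves lists whose genes move together, and the correlation estimated for a real list reached 0.77 (ATF4 targets).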

Results

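The expression of 22976 genes was measured in SFTPC-positive cells sorted from human alveolar organoids after 10 days with vehicle (3 arrays), 5 µM GNE7915 (3 arrays) or 10 µM amiodarone (3 arrays). Between 56.3% and 60.6% of probes were well above background on each array. The Pearson correlation across genes between replicates had a median of 0.985 in the vehicle group, 0.983 in the GNE7915 group and 0.977 in the amiodarone group, against 0.981 between arrays of different groups; genes are not independent replicates. The first principal component held 34.8% of the variance. On it, amiodarone replicate 1 lay at 47.3, among the GNE7915 arrays (16.0 to 71.2). Amiodarone replicates 2 and 3 lay at -31.8 and -39.9, among the vehicle arrays (-43.5 to -5.83). These last 2 arrays were the ones scanned on date 4. The second component held 18.6% of the variance and followed scan date. On it, vehicle replicate 1 (date 1) and GNE7915 replicate 1 (date 2) lay at 41.3 and 39.3. The arrays of date 3 lay from -20.1 to 15.0, and those of date 4 at -36.8 and -41.1. The main fit holds no term for scan date.

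The series is presented as a set of drug toxicology models, and the comparison of GNE7915 with vehicle asks what inhibition of LRRK2 does to the transcripts of alveolar type 2-like cells. CPT1A, which imports long-chain fatty acids into mitochondria, fell by 3.65 on the log2 scale (SE 0.36, 12.6-fold), from -1.18 ± 0.35 (SD, n = 3) to -4.83 ± 0.73 (SD, n = 3). It was well above background on 2 of 3 GNE7915 arrays, so that the size of this fold is uncertain. ECH1, an auxiliary enzyme of the oxidation of unsaturated fatty acids, fell by 1.17 (SE 0.11, 2.24-fold). TREM1, a receptor that amplifies inflammatory signalling, fell by 1.60 (SE 0.11, 3.03-fold), and a second probe of the gene gave -1.58. The antisense RNA VPS9D1-AS1 fell by 1.02 (SE 0.11, 2.03-fold). COL11A2, a collagen chain best known from cartilage, rose by 1.33 (SE 0.13, 2.51-fold), although the least responsive of its 3 probes gave 0.12. The zinc finger gene ZNF540 was at least 1.47-fold higher, since no vehicle array was well above background.

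In limma, 4 genes were higher and 5 lower with GNE7915, and 2975 of 22976 genes had an unadjusted p under 0.05. The adjusted p was 0.0112 for TREM1, 0.025 for CPT1A, ECH1 and COL11A2, and 0.0416 for VPS9D1-AS1 and ZNF540. At these 6 genes all 3 GNE7915 arrays lay on 1 side of the 3 vehicle arrays. The other 3 called transcripts have no approved symbol. One of them was higher by 1.23, and the other 2 were well above background on only 3 of the 9 arrays. With the replicate number as a block, 0 genes passed in limma (4196 at an unadjusted p under 0.05), and the adjusted p of the 6 named genes lay between 0.0785 and 0.0841. This block is balanced over the groups and cannot alter a fold change. With scan date as a block 0 genes passed in limma as well (3334 at an unadjusted p under 0.05). The estimates within date 3 were close to the pooled ones, at -3.93 for CPT1A, -1.24 for ECH1, -1.60 for TREM1, -1.04 for VPS9D1-AS1 and 1.41 for COL11A2. With normexp background correction CPT1A fell by 1.48, and VPS9D1-AS1 (-0.09) and ZNF540 did not pass. Leaving out vehicle replicate 1, 2 or 3, GNE7915 replicate 1 or 3 or amiodarone replicate 2 left 0 genes in limma (2715, 2214, 2627, 3117, 1775 and 2638 at an unadjusted p under 0.05). Without GNE7915 replicate 2 there were 6 lower, without amiodarone replicate 3 there were 1 higher and 1 lower, and without amiodarone replicate 1 there were 4 higher and 10 lower.

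**Figure D1:**
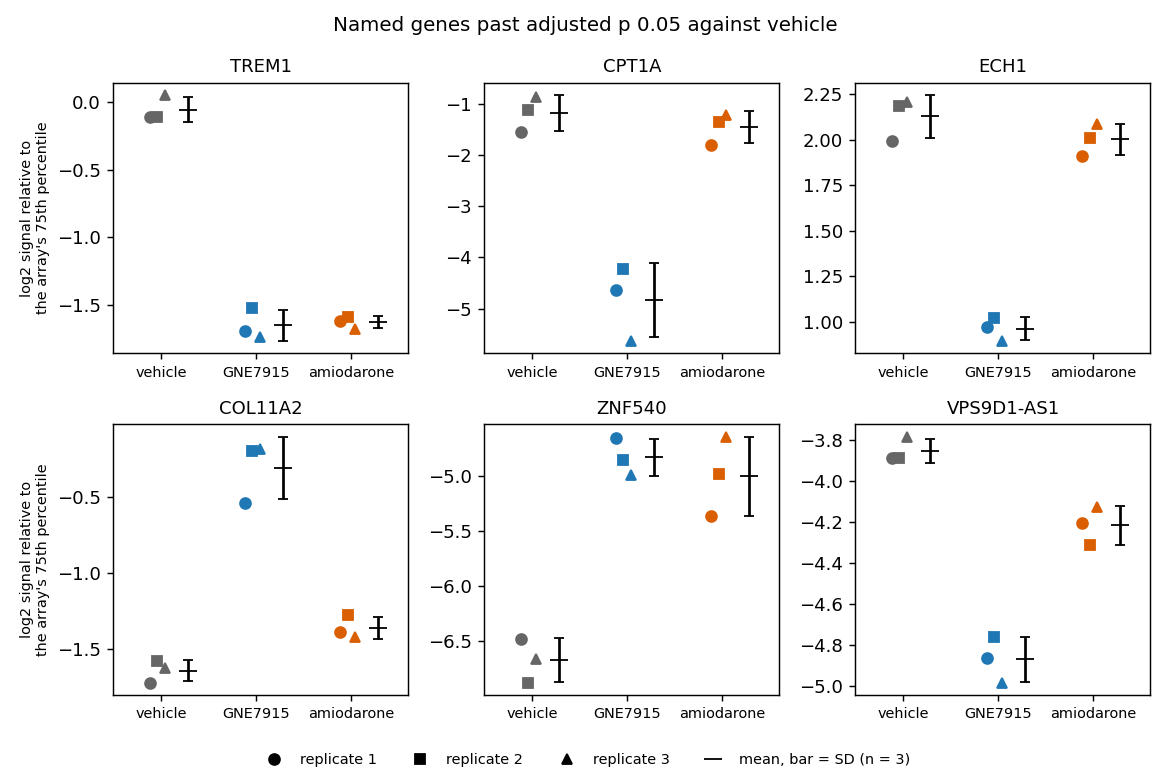
Scaled log2 signal of the 6 named genes that passed the threshold between GNE7915 and vehicle, 1 panel per gene, with each array as a point (shape gives the replicate) and the mean and SD (n = 3) as a bar beside each group; the vertical axes differ between panels and do not start at 0. CPT1A and ECH1 are low in the 3 GNE7915 arrays alone, TREM1 is low in all 6 arrays of the treated groups, with means of -1.65 and -1.63 against -0.06 for vehicle, and ZNF540 is well above background in no vehicle array, so that its axis does not show a fold.

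SFTPC, on which the cells were sorted, did not pass the test with GNE7915 (9.81 ± 0.09 against 9.71 ± 0.19, SD, n = 3; difference 0.10, 95% interval -0.28 to 0.47). SFTPB, the other hydrophobic surfactant protein, differed by 0.07 (-0.22 to 0.36) and NAPSA, an aspartic protease that processes surfactant proteins, by -0.13 (-0.66 to 0.39). The collectins of surfactant did not move alike. SFTPD was lower in all 3 GNE7915 arrays by more than the range of either group (-1.31, SE 0.17), with an adjusted p of 0.0775. SFTPA1 and SFTPA2 both had a difference of 1.61 (SE 0.83 and 0.85, adjusted p = 0.446 and 0.456 in limma), with all 3 GNE7915 arrays above the vehicle arrays. With the replicate number as a block the adjusted p in limma was 0.0785 for SFTPA1 and SFTPA2 and 0.0994 for SFTPD, so that none of them passed. The lamellar body genes ABCA3, a phospholipid transporter, and LAMP3 had differences of 0.92 (SE 0.41) and 0.99 (SE 0.53), LPCAT1, which makes the main surfactant phospholipid, of 0.53 (SE 0.21), and the lung regulator NKX2-1 of 0.39 (SE 0.21). LRRK2 itself, the target of the drug, had a difference of 1.11 (SE 0.61, adjusted p = 0.47), with all 3 GNE7915 arrays above the vehicle arrays. CPM, the marker used to enrich the progenitors, had no matched probe and was not analysed here.

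Over the 17 measured genes of surfactant proteins and the lamellar body, the median change was 0.53 and 13 genes lay above 0, but the list did not pass (adjusted p = 0.265). Adjusted over the list alone, 1 member was lower (SFTPD) and 0 were higher in limma, against 3 lower and 2 higher at an unadjusted p under 0.05. PGC, a progastricsin of type 2 cells, had a change of 1.00 (SE 0.41) and SFTA2 of -0.54 (SE 0.20). With the replicate number as a block the list passed upwards (adjusted p = 0.00299; adjusted p = 0.569 in the same fit with an estimated correlation), and within scan date 3 it did not (median 0.50, adjusted p = 0.431).

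**Figure D2:**
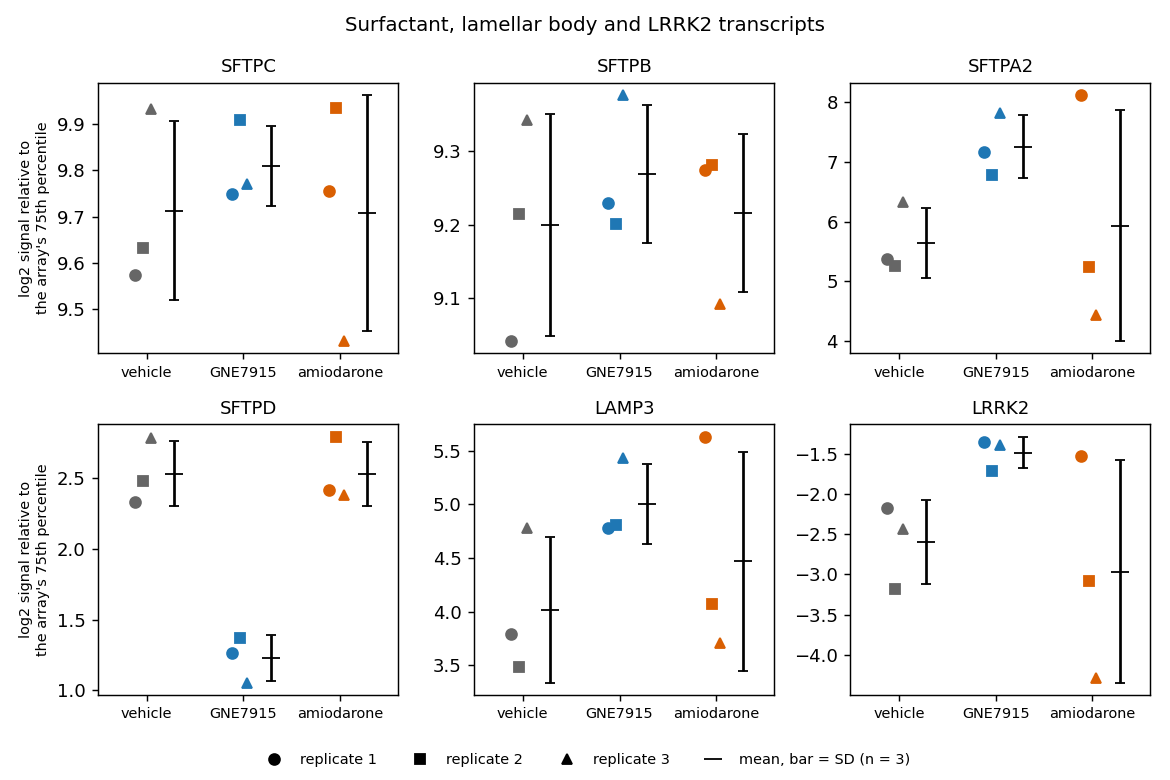
Scaled log2 signal of 4 surfactant genes, the lamellar body gene LAMP3 and LRRK2, 1 panel per gene, with each array as a point (shape gives the replicate) and the mean and SD (n = 3) as a bar beside each group; the vertical axes differ between panels and do not start at 0. SFTPD is lower in the 3 GNE7915 arrays (1.23 ± 0.16) than in all others, and amiodarone replicate 1 stands apart from replicates 2 and 3 of its group for SFTPA2 (8.12 against 5.24 and 4.44), LAMP3 and LRRK2.

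Of the 34 gene lists, 11 passed the preset test with GNE7915, all downwards, and 0 passed upwards. None of these calls held with an estimated correlation in camera (0 lists, lowest adjusted p = 0.299, 2 at an unadjusted p under 0.05) or in fry (0 lists, lowest adjusted p = 0.0979, 10 at an unadjusted p under 0.05). The strongest was hypoxia and glycolysis, whose median fell by 0.49 (adjusted p = 4.51e-06; adjusted p = 0.354 with an estimated correlation). Of its 24 measured genes, 11 were lower at an unadjusted p under 0.05, 7 adjusted over the list alone and 0 over all genes in limma. ANGPTL4, a secreted inhibitor of lipoprotein lipase, had a change of -2.17 (SE 0.47) and the peptide hormone gene ADM of -1.76 (SE 0.51). The oxygen sensor EGLN3 gave -2.07 (SE 0.61) and PDK1, a kinase of pyruvate dehydrogenase, -0.76 (SE 0.17).

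Genes of NF-kappaB and cytokines fell by a median of 0.72 (adjusted p = 8.96e-06; adjusted p = 0.318 with an estimated correlation). Of 20 measured, 9 were lower at an unadjusted p under 0.05 and 0 adjusted over the list alone in limma. IL6 had a change of -1.51 (SE 0.48), BIRC3 of -0.98 (SE 0.23), NFKBIZ of -0.51 (SE 0.16) and IL1B of -2.28 (SE 0.68, with 1 GNE7915 array above background). The interferon list fell by a median of 0.20 (adjusted p = 0.00584; adjusted p = 0.318 with an estimated correlation), with 3 of 23 members lower adjusted over the list alone. OASL (-2.81, SE 0.60), RSAD2 (-1.54, SE 0.38) and IFIT2 (-1.52, SE 0.46) are antiviral effectors and ISG20 (-0.78, SE 0.21) a nuclease. OASL was above background on 1 of 3 GNE7915 arrays, and RSAD2 and IFIT2 on 2 of 3. Targets of p53 fell by a median of 0.30 (adjusted p = 0.00209; adjusted p = 0.299 with an estimated correlation), with 4 of 20 lower adjusted over the list alone. The changes were -1.58 for GADD45A (SE 0.26), -1.34 for PLK3 (SE 0.32), -1.09 for the cell cycle inhibitor CDKN1A (SE 0.27) and -0.99 for the secreted stress factor GDF15 (SE 0.28). With normexp background correction the medians were -0.47 for the NF-kappaB and cytokine list and -0.20 for the p53 list, and both lists passed.

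The 10 targets of the sterol receptor LXR fell by a median of 0.30 (adjusted p = 0.00209; adjusted p = 0.318 with an estimated correlation). Only ABCA1, the cholesterol exporter, was lower adjusted over the list alone (-1.38, SE 0.28), and ABCG1 (-0.49, SE 0.23) and MYLIP (-0.40, SE 0.18) did not pass. The FGF and MAPK feedback genes fell by a median of 0.27 (adjusted p = 0.00209; adjusted p = 0.324 with an estimated correlation), with 6 of 17 members lower at an unadjusted p under 0.05 and 0 adjusted over the list alone in limma. The transcription factor gene FOSL1 gave -2.27 (SE 0.55), DUSP5 -1.24 (SE 0.34), IER3 -1.26 (SE 0.40) and MYC -0.56 (SE 0.19). The 12 glucocorticoid response genes fell by a median of 0.21 (adjusted p = 0.0163; adjusted p = 0.435 with an estimated correlation), and 1 of them, the kinase SGK1 (-0.91, SE 0.22), passed when adjusted over the list alone. ERRFI1 gave -0.69 (SE 0.24), MT1X -0.56 (SE 0.31) and GLUL -0.16 (SE 0.10). This list did not pass within scan date 3 (adjusted p = 0.0586), nor without vehicle replicate 3 or GNE7915 replicate 3 (0.0513 and 0.0773).

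Markers of other lung epithelial cells were lower in the same arrays. The 6 airway basal markers fell by a median of 1.24 (adjusted p = 0.00774; adjusted p = 0.442 with an estimated correlation), and 4 of them were lower adjusted over the list alone. These were KRT14 (-3.27, SE 1.12), KRT17 (-3.39, SE 1.25), TP63 (-1.40, SE 0.40, with 1 GNE7915 array above background) and S100A2 (-1.09, SE 0.40). The ciliated cell markers fell by a median of 1.24 (adjusted p = 0.00199; adjusted p = 0.318 with an estimated correlation), with 3 of 11 lower adjusted over the list alone. The cilium regulator FOXJ1 gave -1.78 (SE 0.52), DNAH5 -2.28 (SE 0.85) and CAPS -0.94 (SE 0.28), and SNTN was at least 1.81-fold lower because no GNE7915 array was above background. The airway secretory and goblet markers fell by a median of 0.94 (adjusted p = 0.00774; adjusted p = 0.299 with an estimated correlation), with 1 of 11, the mucin MUC5B (-1.94, SE 0.33), lower adjusted over the list alone. The goblet cell gene AGR2 gave -1.42 (SE 0.48), MUC1 -0.36 (SE 0.16) and TFF1 -1.01 (SE 0.52). The 13 neuroendocrine markers fell by a median of 1.04 (adjusted p = 0.0214; adjusted p = 0.831 with an estimated correlation), although the member that passed when adjusted over the list alone, UCHL1, a ubiquitin hydrolase, was higher (1.06, SE 0.21). NEUROD1 gave -1.94 (SE 0.74), GRP -1.60 (SE 0.63) and DDC -0.92 (SE 0.26). With normexp background correction the medians were -0.18 for ciliated, -0.52 for basal, -0.42 for secretory and -0.49 for neuroendocrine markers, and all 4 lists passed. The basal list did not pass without vehicle replicate 2 (adjusted p = 0.105). The neuroendocrine list did not pass without vehicle replicate 1 or 2 or GNE7915 replicate 1 (adjusted p = 0.0745, 0.1 and 0.153).

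Lists closest to the aim of the study did not pass with GNE7915. The median change was 0.05 for 41 lysosomal hydrolases (mean -0.04 and test downwards, adjusted p = 0.965), 0.07 for 26 genes of cholesterol synthesis and uptake (adjusted p = 0.554). It was 0.06 for 29 genes of phospholipid synthesis and remodelling (adjusted p = 0.508) and 0.03 for 17 genes of LRRK2 and its substrates and partners (adjusted p = 0.633). In each of the 4 lists 0 members passed in limma when adjusted over the list alone, while 6, 4, 3 and 1 had an unadjusted p under 0.05. Among the hydrolases CTSZ had a change of -0.81 (SE 0.29), PLA2G15, a lysosomal phospholipase, of 0.37 (SE 0.13) and ARSA of -0.29 (SE 0.12). LSS gave 0.48 (SE 0.11), HSD17B7 0.38 (SE 0.14), MVK 0.30 (SE 0.12) and TM7SF2 -0.31 (SE 0.12) among the cholesterol genes, and LPIN2 -0.64 (SE 0.16), LPIN1 0.32 (SE 0.12) and PCYT2 0.34 (SE 0.16) among the phospholipid genes. The LRRK2 substrates RAB10 and RAB3A gave 0.25 (SE 0.11) and 0.36 (SE 0.19), and the partner BAG5 -0.18 (SE 0.11). With the replicate number as a block 14 lists passed, including all 11 above, and with scan date as a block 11 passed, 10 of them shared. With the same replicate block and an estimated correlation 0 passed in camera (lowest adjusted p = 0.486, 0 at an unadjusted p under 0.05).

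**Figure D3:**
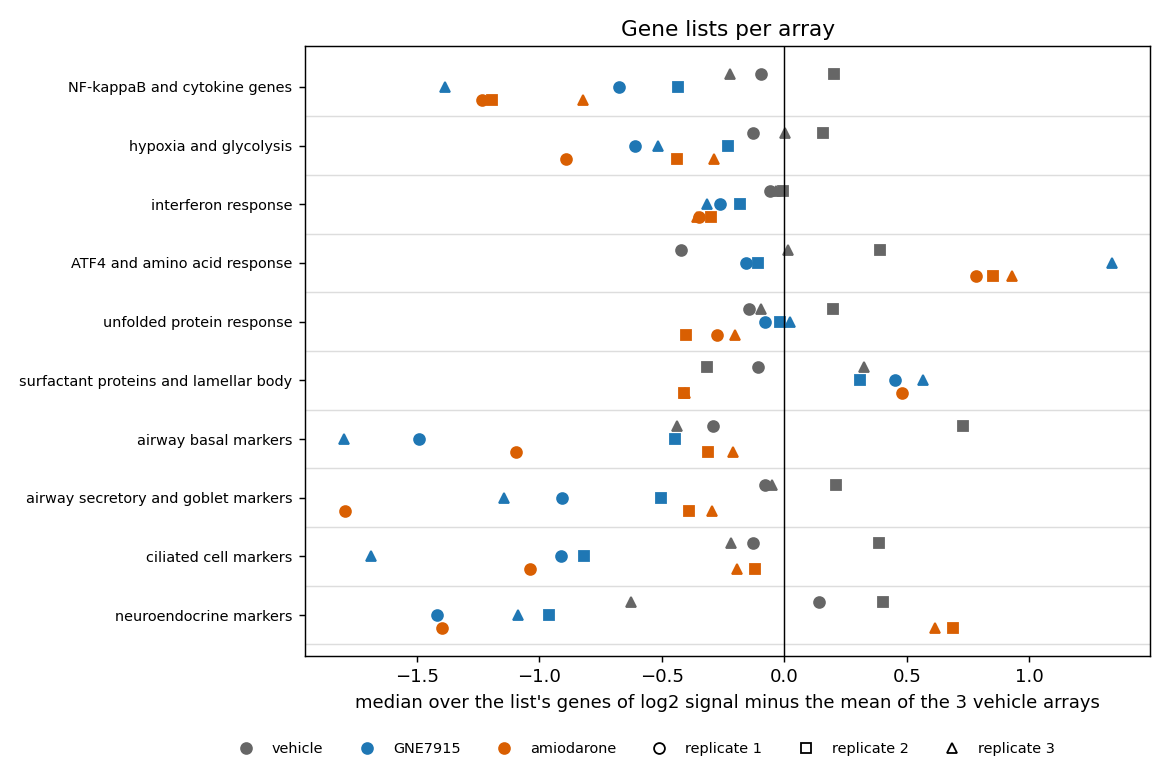
Median over the genes of each of 10 lists of the log2 signal minus the mean of the 3 vehicle arrays, with 1 point per array (colour gives the group, shape the replicate). All 6 arrays of the treated groups lie below the 3 vehicle arrays for the NF-kappaB and cytokine, hypoxia and glycolysis and interferon lists; for the ATF4 list the 3 amiodarone arrays and GNE7915 replicate 3 lie above them, and for the neuroendocrine list amiodarone replicates 2 and 3 (0.69 and 0.62) lie apart from replicate 1 (-1.40).

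Amiodarone, a drug known for lung toxicity and for the storage of phospholipids in lysosomes, was compared with vehicle in the same way. TREM1 fell by 1.57 (SE 0.11, 2.98-fold), from -0.06 ± 0.09 to -1.63 ± 0.05 (SD, n = 3), with an adjusted p of 0.0126 and all 3 amiodarone arrays below the vehicle arrays. In limma it was the 1 gene lower, 0 genes were higher, and 3080 of 22976 had an unadjusted p under 0.05. The smallest p values among the genes higher with amiodarone were those of the tumour suppressor LZTS1 (1.22, SE 0.14, adjusted p = 0.0846), ZNF540 (at least 1.31-fold higher), EPM2AIP1 (1.19, SE 0.16), the small nucleolar RNA SNORD15A (1.65, SE 0.24) and CDKL2 (0.76, SE 0.11). TREM1 differed by -1.59 within scan date 3, where 1 amiodarone array stands against 2 vehicle arrays, and with scan date as a block 0 genes passed in limma (2702 at an unadjusted p under 0.05). Leaving out vehicle replicate 1, 2 or 3 or amiodarone replicate 2 or 3 left 0 genes in limma (2625, 2424, 2527, 2015 and 2201 at an unadjusted p under 0.05). Without GNE7915 replicate 1 or 2 there were 2 lower, and without amiodarone replicate 1 there were 4 higher and 15 lower.

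The surfactant genes of amiodarone-treated cells had group means close to those of vehicle. SFTPC differed by -0.01 (95% interval -0.38 to 0.37), SFTPB by 0.02 (-0.27 to 0.31), SFTPD by 0.00 (-0.40 to 0.40), LPCAT1 by -0.07 (-0.55 to 0.41) and NKX2-1 by 0.20 (-0.29 to 0.68). NAPSA differed by -0.40 (SE 0.23) and ABCA3 by -0.18 (SE 0.41). For several genes the mean hid a wide spread, as SFTPA2 was 5.93 ± 1.94 and SFTPA1 0.77 ± 1.91 (SD, n = 3), with 8.12 and 2.96 in replicate 1 against 4.44 to 5.24 and -0.55 to -0.09 in the other 2. LAMP3 (0.45, SE 0.53) was likewise higher in replicate 1 (5.63 against 3.71 to 4.07), as was LRRK2 (-0.37, SE 0.61), with -1.53 against -4.28 to -3.08. Within scan date 3, which holds replicate 1 alone of this group, the differences were 2.33 for SFTPA2, 2.48 for SFTPA1, 1.50 for LAMP3 and 1.28 for LRRK2, so that the direction of LRRK2 turned. The surfactant and lamellar body list had a median of -0.03 (adjusted p = 0.524), which lay between -0.10 and 0.03 across the scalings tried. Its median was 0.48 in replicate 1 and -0.41 and -0.40 in replicates 2 and 3, and within scan date 3 it was 0.48 (adjusted p = 0.183). Its member DMBT1, a scavenger receptor-like glycoprotein, was the only one lower when adjusted over the list alone, at least 2.82-fold, with no amiodarone array above background, and the protease gene CTSH gave 0.46 (SE 0.17) and CKAP4 -0.28 (SE 0.22).

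With amiodarone 11 lists passed the preset test, 2 upwards and 9 downwards. With an estimated correlation 0 passed in camera (lowest adjusted p = 0.399, 3 at an unadjusted p under 0.05), and 0 passed in fry (lowest adjusted p = 0.0833, 8 at an unadjusted p under 0.05). Values within scan date 3 rest on replicate 1 alone of this group, here and below, so that they support no call. Targets of ATF4, the transcription factor of the integrated stress and amino acid response, rose by a median of 0.82 (adjusted p = 5.1e-08; adjusted p = 0.64 with an estimated correlation). All 25 measured members lay above 0, 9 of them at an unadjusted p under 0.05 and 0 adjusted over the list alone in limma. TRIB3 gave 1.45 (SE 0.43), CHAC1, which degrades glutathione, 1.76 (SE 0.52), NUPR1 1.09 (SE 0.37) and STC2 1.65 (SE 0.61). The list medians of the 3 amiodarone arrays (0.78, 0.85 and 0.93) lay above those of the vehicle arrays (-0.42 to 0.39), whereas within scan date 3 the median was 0.60 and the list did not pass (adjusted p = 0.0927). The unfolded protein response list fell by a median of 0.35 (adjusted p = 4.94e-05; adjusted p = 0.42 with an estimated correlation), with 6 of 21 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone in limma. Its chaperone genes HSP90B1 (-0.53, SE 0.13), MANF (-0.49, SE 0.15), SDF2L1 (-0.73, SE 0.26) and PDIA4 (-0.48, SE 0.18) serve protein folding in the endoplasmic reticulum.

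The 41 lysosomal hydrolases rose by a median of 0.06 (adjusted p = 0.0497; adjusted p = 0.736 with an estimated correlation; adjusted p = 0.562 with scan date as a block), with 9 higher and 2 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone in limma. The protease CTSL gave 0.46 (SE 0.15), MAN2B1 0.43 (SE 0.13), the sialidase NEU1 0.31 (SE 0.11) and the acid lipase LIPA -0.35 (SE 0.12). The list passed in 8 of 23 alternatives. It did not pass without vehicle replicate 1 or 3, GNE7915 replicate 2 or 3 or amiodarone replicate 2 or 3 (adjusted p from 0.0547 to 0.305). Targets of the antioxidant regulator NRF2 fell by a median of 0.18 (adjusted p = 0.00445; adjusted p = 0.42 with an estimated correlation), with 3 of 22 lower adjusted over the list alone. Across scalings this median ran from -0.20 to -0.12. The glutathione peroxidase GPX2 gave -1.27 (SE 0.17), NQO1 -1.10 (SE 0.30) and ME1 -0.56 (SE 0.17), and AKR1B10 was at least 4.83-fold lower. Genes of phospholipid synthesis and remodelling (median 0.05, mean -0.01 and test downwards, adjusted p = 1) and of cholesterol synthesis and uptake (median -0.05, from -0.09 to 0.01 across scalings, adjusted p = 0.551) did not pass, and in each of them 0 members passed adjusted over the list alone in limma (3 and 2 at an unadjusted p under 0.05). Among phospholipid genes LPIN2 gave -0.64 (SE 0.16), LPCAT2 -1.06 (SE 0.30), PGS1 -0.32 (SE 0.12) and SELENOI -0.30 (SE 0.14). Among cholesterol genes LSS gave 0.34 (SE 0.11), MSMO1 -0.55 (SE 0.19), PMVK 0.25 (SE 0.13) and MVD 0.22 (SE 0.13). The list of LRRK2 and its partners did not pass either (median 0.05, adjusted p = 0.505), with RAB3A at 0.59 (SE 0.19), RAB29 at 0.55 (SE 0.20), RILPL1 at 0.36 (SE 0.18) and GAK at 0.20 (SE 0.11).

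Hypoxia and glycolysis genes fell by a median of 0.57 with amiodarone (adjusted p = 9.99e-09; adjusted p = 0.42 with an estimated correlation), and 11 of 24 were lower adjusted over the list alone. The glycolytic enzyme genes LDHA (-0.92, SE 0.16), HK2 (-1.22, SE 0.25) and GPI (-0.48, SE 0.10) and the kinase PDK1 (-0.87, SE 0.17) were among these. NF-kappaB and cytokine genes fell by a median of 0.92 (adjusted p = 4.51e-08; adjusted p = 0.42 with an estimated correlation), with 10 of 20 lower and 1, NFKBIZ (0.62, SE 0.16), higher adjusted over the list alone. The chemokine CCL20 gave -2.89 (SE 0.79) and the apoptosis inhibitor BIRC3 -1.48 (SE 0.23), and TNF was at least 2.56-fold lower, with no amiodarone array above background. The interferon list fell by a median of 0.21 (adjusted p = 0.00557; adjusted p = 0.42 with an estimated correlation), with 1 of 23, IFITM1 (-1.36, SE 0.30), lower adjusted over the list alone. OAS3 gave -0.69 (SE 0.19), ISG20 -0.74 (SE 0.21) and OASL -1.46 (SE 0.60, with 1 amiodarone array above background). The interferon median ran from -0.21 to -0.03 across scalings. Glucocorticoid response genes fell by a median of 0.29 (adjusted p = 0.00721; adjusted p = 0.42 with an estimated correlation), and FKBP5, the chaperone induced by glucocorticoids, was the 1 of 12 lower adjusted over the list alone (-1.02, SE 0.14). SGK1 gave -0.50 (SE 0.22), ERRFI1 -0.47 (SE 0.24) and KLF9 -0.29 (SE 0.16). The adjusted p of these 4 lists within scan date 3, on replicate 1 alone and at the preset correlation, were 9.49e-12, 6.67e-05, 0.00036 and 0.00193. Without amiodarone replicate 1 the interferon list (median -0.49, adjusted p = 0.0681) and the glucocorticoid list (-0.16, 0.131) did not pass.

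Targets of p53 fell by a median of 0.27 with amiodarone (adjusted p = 0.00471; adjusted p = 0.399 with an estimated correlation), with 7 of 20 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone in limma. PHLDA3 gave -1.04 (SE 0.27), GADD45A -0.88 (SE 0.26), RRM2B -0.42 (SE 0.13) and FAS -0.93 (SE 0.29), and within scan date 3 the list did not pass (adjusted p = 0.183). Proliferation genes fell by a median of 0.16 (adjusted p = 0.012; adjusted p = 0.819 with an estimated correlation), with MCM6 at -0.69 (SE 0.26), MCM4 at -0.60 (SE 0.26), PCNA at -0.52 (SE 0.23) and UHRF1 at -0.63 (SE 0.28). Of the 33 measured, 2 were lower at an unadjusted p under 0.05 and 0 adjusted over the list alone in limma, and within scan date 3 the median was 0.11 in the opposite direction (adjusted p = 0.839). Without amiodarone replicate 3 the list did not pass (adjusted p = 0.958). The airway secretory and goblet markers fell by a median of 0.82 (adjusted p = 0.00436; adjusted p = 0.399 with an estimated correlation), with 1 of 11, MUC5B (-1.65, SE 0.33), lower adjusted over the list alone. The club cell gene SCGB1A1 gave -1.37 (SE 0.67), AGR2 -1.05 (SE 0.48) and TFF1 -1.20 (SE 0.52). The secretory median was -1.79 in replicate 1 and -0.39 and -0.29 in replicates 2 and 3. Over all alternatives it ran from -1.98 to -0.28. In the basal list DLK2 was the 1 member that passed adjusted over the list alone, and it was higher (0.85). Basal (median -0.79, adjusted p = 0.567), ciliated (-0.30, up to 0.04 across scalings, adjusted p = 0.137) and neuroendocrine markers (0.03, adjusted p = 0.723) did not pass. For the ciliated list the medians were -1.04 in replicate 1 and -0.12 and -0.19 in replicates 2 and 3. Within scan date 3, on replicate 1 alone and at the preset correlation, the medians were -1.29 for the ciliated list (adjusted p = 0.00193) and -1.27 for the neuroendocrine list (adjusted p = 0.000138). The neuroendocrine medians of replicates 2 and 3 were 0.69 and 0.62. With scan date as a block 12 lists passed, of which 7 were among the 11 above.

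The direct comparison of amiodarone with GNE7915 asks at which genes the drugs differ. In limma 0 genes were higher and 0 lower, with 3064 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0572. The genes with the smallest p were, above GNE7915, CPT1A (3.38, SE 0.36, adjusted p = 0.0679), ECH1 (1.04, SE 0.11), ZNF334 (0.94, SE 0.11), CEBPA-DT (0.87, SE 0.11) and LZTS1 (1.08, SE 0.14). Below it were SELPLG, a selectin ligand (-1.42, SE 0.14, adjusted p = 0.0572), the mitochondrial fission gene MTFR2 (-1.36, SE 0.16), the adrenergic receptor ADRA2C (-1.45, SE 0.17) and COL11A2 (-1.05, SE 0.13). Amiodarone and GNE7915 arrays did not overlap at any of these genes. Without amiodarone replicate 1, 173 genes were higher and 201 lower in limma, and without vehicle replicate 3, 6 were lower.

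SFTPD was higher with amiodarone than with GNE7915 by 1.31 (SE 0.17, adjusted p = 0.0821), whereas SFTPC (-0.10), SFTPB (-0.05), NAPSA (-0.27) and NKX2-1 (-0.19) differed by less than 2 SE. The differences were -1.32 for SFTPA1 (SE 0.83), -1.32 for SFTPA2 (SE 0.85), -0.54 for LAMP3 (SE 0.53), -1.10 for ABCA3 (SE 0.41), -0.60 for LPCAT1 (SE 0.21) and -1.48 for LRRK2 (SE 0.61). Within scan date 3, where only replicate 1 stands for amiodarone, they were 0.91, 0.82, 0.51, -0.43, -0.32 and 0.02. The surfactant and lamellar body list had a median of -0.60 and an adjusted p of 0.05, just short of the threshold, with SFTPD, higher, its only member adjusted over the list alone. Within scan date 3 the median turned, to 0.17 (adjusted p = 0.55). PGC gave -1.19 (SE 0.41), and for DMBT1 the arrays above background were 2 of 3 with GNE7915 and 0 of 3 with amiodarone.

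Between the drugs 9 lists passed the preset test, 5 higher with amiodarone and 4 lower. In camera 0 passed with an estimated correlation, also at an unadjusted p under 0.05 (0 lists); each of the 9 had an adjusted p = 0.755 with an estimated correlation. In fry 0 passed (lowest adjusted p = 0.113, 2 at an unadjusted p under 0.05). Values within scan date 3 rest on replicate 1 alone of the amiodarone group, here and below, so that they support no call. LXR targets were higher by a median of 0.48 (adjusted p = 0.00408; within scan date 3 median 0.44, adjusted p = 0.014). Adjusted over the list alone, ABCA1 (1.57, SE 0.28), MYLIP (0.93, SE 0.18) and APOE (0.61, SE 0.17) were among the 4 members higher and SMPDL3A (-0.47, SE 0.14) was the 1 lower. ATF4 targets were higher by a median of 0.48 (adjusted p = 0.00122), with 2 of 25 higher adjusted over the list alone, AARS1 (0.79, SE 0.16) and NUPR1 (1.50, SE 0.37), beside ATF3 (1.02, SE 0.42) and TRIB3 (0.96, SE 0.43). GNE7915 replicate 3 had an ATF4 median of 1.34 against -0.16 and -0.11 in the other 2, and within scan date 3 the list did not pass (median 0.06, adjusted p = 0.516). Nor did it pass without GNE7915 replicate 1 or 2 (0.0838 and 0.0718). Lysosomal hydrolases were higher by a median of 0.10 (adjusted p = 0.0467; within scan date 3 adjusted p = 0.446), with MAN2B1 at 0.48 (SE 0.13), CTSL at 0.52 (SE 0.15) and LGMN at -0.58 (SE 0.19). Of the 41 measured, 8 were higher and 1 lower at an unadjusted p under 0.05, and 0 adjusted over the list alone in limma. The hydrolase list did not pass without vehicle replicate 1, GNE7915 replicate 1 or 3 or amiodarone replicate 2 or 3 (adjusted p from 0.0543 to 0.283).

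The unfolded protein response list was lower with amiodarone than with GNE7915 by a median of -0.29 (adjusted p = 0.00322; within scan date 3 adjusted p = 0.00107), with MANF (-0.51, SE 0.15), HSP90B1 (-0.42, SE 0.13), DNAJB11 (-0.43, SE 0.14) and DNAJC3 (-0.45, SE 0.15) below GNE7915 in all arrays. The NRF2 list was lower by -0.22 (adjusted p = 0.0467; within scan date 3 adjusted p = 0.0344), with NQO1 at -1.26 (SE 0.30), GPX2 at -0.59 (SE 0.17) and TALDO1 at -0.31 (SE 0.12). It passed in 10 of 23 alternatives, and of the 9 fits without a single array only in 2 (adjusted p up to 0.366). Fibroblast and mesenchyme markers were lower by -0.40 (adjusted p = 0.0253), with TCF21 at -0.93 (SE 0.25), LUM at -0.85 (SE 0.23), PDGFRA at -1.01 (SE 0.32) and COL5A2 at -0.62 (SE 0.27). Across scalings this median ran from -0.40 to -0.08, and the list did not pass without GNE7915 replicate 2 (-0.21, adjusted p = 0.257) or amiodarone replicate 1 (-0.10, adjusted p = 0.491). In these 3 lists 0 members passed in limma adjusted over the list alone, with 7, 4 and 5 lower at an unadjusted p under 0.05. Proliferation genes were lower by -0.26 (adjusted p = 0.00238), with MCM6 at -0.59 (SE 0.26), AURKA at -0.51 (SE 0.23), CDK1 at -0.37 (SE 0.18) and MCM2 at -0.43 (SE 0.22). Of these genes 0 of 33 had an unadjusted p under 0.05 in limma. Basal markers were higher by 0.76 (adjusted p = 0.0467), with DLK2 (0.88, SE 0.20) higher adjusted over the list alone and KRT14 (1.78, SE 1.12), KRT17 (1.96, SE 1.25) and TP63 (0.63, SE 0.40) short of it. Neuroendocrine markers were higher by 1.06 (adjusted p = 0.0237), with GRP at 2.25 (SE 0.63), NEUROD1 at 2.36 (SE 0.74), CHGA at 2.20 (SE 0.89) and DDC at 0.81 (SE 0.26). Of the 13 measured, 5 were higher at an unadjusted p under 0.05 and 0 adjusted over the list alone in limma. Within scan date 3 the medians of these last 3 lists turned, to 0.06 for proliferation (adjusted p = 0.722), -0.19 for basal markers (with the test still upwards, adjusted p = 0.659) and -0.39 for neuroendocrine markers (adjusted p = 0.114). Without GNE7915 replicate 2 or amiodarone replicate 3 proliferation did not pass (0.073 and 0.245). Basal markers did not pass without vehicle replicate 1, GNE7915 replicate 1 or 3 or amiodarone replicate 2 or 3 (0.063 to 0.308). Neuroendocrine markers did not pass without GNE7915 replicate 1 or amiodarone replicate 2 or 3 (0.0838, 0.0882 and 0.182). With normexp background correction the medians were smaller, at 0.39 for basal and 0.50 for neuroendocrine markers. With scan date as a block 6 lists passed, 4 of them among the 9.

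In the core lipid lists amiodarone and GNE7915 did not differ past the threshold. The median was -0.13 for cholesterol synthesis and uptake (adjusted p = 0.167), with HSD17B7 at -0.48 (SE 0.14), PMVK at 0.41 (SE 0.13), TM7SF2 at 0.32 (SE 0.12) and ACAT2 at -0.48 (SE 0.19). It was -0.07 for phospholipid synthesis and remodelling (adjusted p = 0.404), with PCYT1A at -0.53 (SE 0.18), LPCAT3 at 0.36 (SE 0.14) and SELENOI at -0.32 (SE 0.14). For LRRK2 and its partners it was 0.07 (mean -0.02, adjusted p = 0.711), with RILPL1 at 0.43 (SE 0.18), BAG5 at 0.23 (SE 0.11) and RAB10 at -0.20 (SE 0.11).

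Both drugs lowered 1 gene in common, TREM1, and raised 0 in common in limma, where lists of these sizes drawn independently would share 0.000218 genes. At an unadjusted p under 0.05, 908 genes moved in the same direction with both drugs. Across genes, the log2 fold changes of the drugs correlated with r = 0.53, where genes are not independent replicates and both fold changes share the vehicle arrays. In simulated data without any drug effect the mean correlation was 0.478 and the mean number of such genes 375, and 15 of 100 draws reached 908 genes or more. The covariance of the fold changes was 0.113 against a simulated mean of 0.062, and 17 of 100 draws reached it. Agreement this large across all genes thus also arose without a drug effect. The simulation shares the vehicle arrays and keeps the correlations between genes, and these were not told apart. Only 1 of 100 draws had any shared call, but that draw had 819, so that the simulated mean of 8.19 lay above the observed 1. With the replicate number or scan date as a block 0 genes were shared in limma, where 0 passed with either drug.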

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

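The alternatives chosen after the data had been seen were scan date as a random block, the arrays of scan date 3 alone, the arrays of Feature Extraction 12 alone, the replicate block of the vehicle and GNE7915 arrays alone, also with an estimated correlation for the gene lists, and scan date as a fixed block for the gene lists. Over all alternatives, 1991 of 2414 list results kept their direction and their side of the threshold, 163 uncalled ones changed sign, 157 lost and 95 gained a call, and 8 reversed. Of 4719 results of named genes, 4474 kept both, 51 uncalled ones changed sign, 95 lost and 99 gained a call, and 0 reversed. Most of the 4474 were uncalled results that stayed uncalled. Only 6 named genes with GNE7915 and 1 with amiodarone had a call to lose, and each passed in 3 to 11 of its 21 or 22 alternatives. No scaling moved the median of all genes by 0.1 or more. The cause was not tested for any change below, unless it is named.

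The genes higher and lower with GNE7915 (4 and 5) became 4 and 3 with quantile normalization, 2 and 3 with median scaling, 1 and 5 with normexp background correction, 1 and 2 with only the 2 groups compared, 5 and 8 with array weights, and 6 and 11 with scan date as a random block. With every probe tested 3 were lower. In limma 0 were higher and 0 lower with no filter on dim probes, with the replicate block of all arrays (2989 at an unadjusted p under 0.05) or of the vehicle and GNE7915 arrays alone (4196), with scan date as a fixed block (3334), with only scan date 3 and with only Feature Extraction 12. Without single arrays there were 0 to 4 higher and 0 to 10 lower. TREM1 passed in 11 of 22 alternatives (-1.76 to -1.19), CPT1A in 9 of 21 (-3.96 to -1.48), ECH1 in 8 of 22 (-1.24 to -1.13), COL11A2 in 7 of 22 (0.97 to 1.45), ZNF540 in 7 of 21 and VPS9D1-AS1 in 3 of 22 (-1.07 to -0.09). CPT1A, VPS9D1-AS1, ZNF540 and 2 called transcripts without a symbol lay near background, which limits their values.

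The genes higher and lower with amiodarone (0 and 1) became 4 and 15 with normexp and 166 and 195 with array weights, which gave amiodarone replicate 1 a weight of 0.42 and replicate 2 one of 2.87. With only the 2 groups compared 5 were lower. In limma 0 were lower with median scaling, no filter, the mean of a gene's probes, the replicate block, scan date as a fixed block, only scan date 3 and only Feature Extraction 12. Without single arrays there were 0 to 4 higher and 0 to 15 lower. Between amiodarone and GNE7915 (0 and 0) there were 15 higher and 11 lower with normexp, 5 and 7 with a filter on all 9 arrays, 671 and 595 with array weights and 9 and 7 with a mean-variance trend. Only lower genes appeared with quantile normalization (1), the value table of the authors (2), only the 2 groups compared (1) and scan date as a random block (2). Without single arrays there were 0 to 173 higher and 0 to 201 lower.

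The 1 gene changed by both drugs became 4 with array weights and 0 with median scaling, no filter, the mean of a gene's probes, the replicate block, scan date as a fixed block, only scan date 3 and only Feature Extraction 12, and 0 to 2 without single arrays. Lists past the threshold fell to 0 with an estimated correlation and 0 in fry in all 3 comparisons. With the replicate block of the vehicle and GNE7915 arrays alone and an estimated correlation they fell to 0 in camera (0 at an unadjusted p under 0.05, lowest adjusted p = 0.486). Between the drugs (9) they were 5 with a filter on all 9 arrays, 3 with only Feature Extraction 12 and 4 to 12 without single arrays. They were 10 to 15 of 34 with GNE7915 and 10 to 13 with amiodarone without single arrays. The median correlation of replicates was 0.868 on the 1000 most variable genes against 0.983 on all genes.

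The 8 reversals were of 2 lists. With amiodarone, proliferation turned upwards with scan date as a fixed block (adjusted p = 0.839) and on scan date 3 alone (0.67), and neuroendocrine markers turned downwards (0.000138 and 0.000252). Between amiodarone and GNE7915, proliferation turned upwards (0.722 and 0.672) and neuroendocrine markers downwards (0.114 and 0.121). In both settings amiodarone is represented by replicate 1 alone. On scan date 3 alone its spread is taken from the other groups, and with the block also from amiodarone replicates 2 and 3. Over all alternatives the adjusted p of these lists ran from 2.52e-05 to 0.958 for proliferation with amiodarone, and between the drugs from 2.59e-07 to 0.755 for proliferation and from 7.33e-06 to 0.755 for neuroendocrine markers. Same-numbered GNE7915 and amiodarone arrays did not deviate together (-0.22, 0.12 and -0.36 across genes), nor did those of vehicle and amiodarone (-0.09, 0.18 and -0.27). No pair block was therefore used for them alone. Amiodarone replicate 1 did deviate together with GNE7915 replicate 3 (0.413) and vehicle replicate 3 (0.395), which bear another number.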

Other observations

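The tests chosen only after results were seen were those of scan date, airway cells, a GNE7915 array among the amiodarone arrays and the fatty acid oxidation and PPAR lists, while the splits and regroupings of the arrays were planned. Genes in this paragraph were chosen after their values were seen, as large changes at which the 3 arrays of the drug did not overlap the 3 of vehicle; 20.5% of genes with GNE7915 and 21.8% with amiodarone did not overlap, against the 10% that chance gives for 3 against 3. None passed the threshold. The chemokine CXCL14 was lower with GNE7915 (-4.76, SE 0.99, adjusted p = 0.162) and with amiodarone (-5.50, SE 0.99, adjusted p = 0.144), and the matrix protease MMP7 gave -2.94 (SE 0.91) and -2.60 (SE 0.91). With GNE7915 the WNT inhibitor WIF1 gave 2.31 (SE 0.88), the hedgehog ligand IHH 2.30 (SE 0.97), SORCS1 2.98 (SE 0.97) and the cilium gene TEKT2 -2.90 (SE 0.59). With amiodarone the complement component C3 gave -2.85 (SE 0.45), the fatty acid receptor CD36 1.78 (SE 0.50), the amino acid transporter SLC7A3 1.99 (SE 0.53) and the basement membrane gene NID2 1.77 (SE 0.29). Within scan date 3 these were -4.57 and -5.05 for CXCL14, -3.34 and -4.37 for MMP7, 2.37 for WIF1, 2.46 for IHH, 3.19 for SORCS1, -2.84 for TEKT2, -2.11 for C3, 3.14 for CD36, 2.57 for SLC7A3 and 2.52 for NID2.

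The lists not described above did not pass without a block, and some medians near 0 changed sign between scalings. With GNE7915 the median change was -0.48 for the TGF-beta response (adjusted p = 0.0563), -0.40 for alveolar type 1 markers (0.0761) and -0.33 for aryl hydrocarbon receptor and xenobiotic metabolism (0.0761). It was -0.11 for lung epithelial transcription factors and progenitor genes (0.101), 0.13 for the respiratory chain (0.111), 0.45 for ATF4 targets (0.112), 0.05 for proliferation (0.561), 0.04 for autophagy (0.581), 0.02 for fatty acid synthesis and desaturation (0.994), 0.18 for fibroblast and mesenchyme markers (0.581), 0.24 for WNT targets (0.626) and -0.38 for liver and gut markers (0.403). Median, mean and test differed in sign for the vacuolar ATPase (0.08, mean -0.14, test up, 0.581), pluripotency markers (0.22, mean -0.07, test up, 0.862), lysosomal membrane proteins (0.03, mean -0.02, test down, 0.862), the unfolded protein response (0.02, mean -0.08, test down, 0.581), NRF2 targets (0.05, mean -0.21, test down, 0.508) and endothelial and blood cell markers (-0.16, mean -0.23, test up, 0.965). Across scalings the median of fatty acid synthesis ran from -0.01 to 0.04 and that of endothelial and blood cell markers from -0.16 to 0.08. With the replicate block of the vehicle and GNE7915 arrays the TGF-beta response (0.00881; 0.486 with an estimated correlation) and alveolar type 1 markers (0.00752; 0.679) passed. Alveolar type 1 markers also passed within scan date 3 (-0.47, 0.0173), and the TGF-beta response did not (-0.35, 0.317). In these lists 2 members passed adjusted over the list alone, the vacuolar ATPase subunit ATP6V1B1 (-3.29) and the monocyte marker CD14 (1.92).

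With amiodarone the median was -0.27 for fibroblast and mesenchyme markers (adjusted p = 0.0505), -0.06 for fatty acid synthesis and desaturation (0.126), -0.17 for aryl hydrocarbon receptor and xenobiotic metabolism (0.134), -0.23 for FGF and MAPK feedback (0.148) and -0.25 for the TGF-beta response (0.315). It was 0.11 for LXR targets (0.723), 0.06 for the respiratory chain (0.735), 0.02 for autophagy (0.778), 0.03 for lysosomal membrane proteins (0.801), -0.06 for lung epithelial transcription factors and progenitor genes (0.801), -0.01 for WNT targets (0.524), 0.03 for liver and gut markers (0.778), -0.05 for alveolar type 1 markers (0.723, mean 0.00) and -0.24 for endothelial and blood cell markers (0.505). The vacuolar ATPase (0.07, mean -0.12, test up, 0.99) and pluripotency markers (-0.03, mean -0.04, test up, 0.949) differed in sign. Across scalings the medians ran from -0.06 to 0.00 for lung epithelial transcription factors, -0.05 to 0.01 for alveolar type 1 markers, -0.08 to 0.00 for fatty acid synthesis, -0.01 to 0.13 for the vacuolar ATPase, 0.00 to 0.08 for autophagy, -0.01 to 0.10 for WNT targets, -0.03 to 0.17 for pluripotency markers and -0.24 to 0.10 for endothelial and blood cell markers. The fibroblast (-0.58, 0.00192), alveolar type 1 (-0.54, 0.00192) and xenobiotic lists (-0.25, 0.0271) passed within scan date 3, which rests on amiodarone replicate 1 alone. The list of fibroblast and mesenchyme markers also passed with each of 4 other scalings, but not without amiodarone replicate 1 (-0.05, 0.636). Adjusted over the list alone, the vacuolar ATPase subunit ATP6V0A4 (-1.66), CYP1B1 of xenobiotic metabolism (-1.62) and the apolipoprotein APOA1 (1.06) passed.

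Between amiodarone and GNE7915 the median was -0.32 for NF-kappaB and cytokine genes (adjusted p = 0.222), -0.13 for hypoxia and glycolysis (mean 0.04, test down, 0.383), 0.13 for the interferon response (0.808), -0.04 for p53 targets (mean 0.05, test up, 0.812) and 0.04 for glucocorticoid response genes (test down, 0.88). It was 0.55 for ciliated (0.119), -0.07 for secretory (mean 0.08, test down, 0.901), 0.36 for alveolar type 1 (0.218), 0.19 for liver and gut (0.216), 0.04 for pluripotency (0.997) and -0.07 for endothelial and blood cell markers (0.317). The others were lung epithelial transcription factors at 0.34 (0.213), fatty acid synthesis at -0.08 (0.119), lysosomal membrane proteins at 0.07 (0.711), the vacuolar ATPase at -0.02 (mean 0.01, test down, 0.711), autophagy at -0.02 (0.812), the respiratory chain at -0.08 (0.246), xenobiotic metabolism at 0.20 (mean -0.09, test up, 0.812), the TGF-beta response at 0.21 (0.445), FGF and MAPK feedback at 0.18 (0.205) and WNT targets at -0.22 (0.213). Across scalings the medians of the vacuolar ATPase (-0.06 to 0.02), autophagy (-0.04 to 0.02), pluripotency (0.00 to 0.07) and endothelial and blood cell markers (-0.07 to 0.02) changed sign. Hypoxia and glycolysis (-0.40, 7.15e-05) and FGF and MAPK feedback (0.38, 0.0151) passed within scan date 3, again on amiodarone replicate 1 alone. Adjusted over the list alone, 4 of 14 liver and gut markers were higher with amiodarone, namely ALB (3.50), AFP (2.00), SERPINA1 (1.08) and APOA1 (0.67). In other lists NFKBIZ (1.13), CYP3A7 (1.02, with 1 GNE7915 array above background), MAP1LC3A (0.66) and TP53I3 (0.67) were higher in the same way. Lower were CXCL5 (-0.75), OAS3 (-1.05), GPI (-0.58), HK2 (-1.50), CYP1B1 (-1.67), FKBP5 (-0.85) and CD14 (-1.63), and also TNF and OAS2, for which no amiodarone array was above background.

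A fall of the NF-kappaB and cytokine list and of the hypoxia and glycolysis list with both drugs is a hypothesis. Both lists passed only with a preset correlation. The glycolytic enzyme genes that fell with amiodarone did not move alike with GNE7915. There LDHA was lower than in vehicle (4.49 to 4.66 against 4.81 to 5.33) and GPI higher (3.67 to 3.74 against 3.58 to 3.64). HK2 overlapped vehicle (-0.83 to 0.17 against -0.61 to -0.40). Within date 3, with 2 GNE7915 arrays against 2 of vehicle, both lists were lower (higher adjusted p = 0.00147 in camera, at the preset correlation). The medians there were -0.845 for the cytokine list and -0.47 for the glycolysis list, and scan date does not part these arrays. Both lists were picked for passing in a fit that includes these arrays, which favours a fall within date 3. Scan date as the cause is therefore not settled for GNE7915. For amiodarone it stays open, as date 3 holds 1 array of that group (higher adjusted p = 6.67e-05). Fewer airway cells, which can make such cytokines but which the sort on SFTPC was meant to remove, may also lower the cytokine list and stay open for both drugs: the 3 GNE7915 arrays were low in ciliated markers too, the highest median being -0.82. The 2 amiodarone arrays of date 4 had basal and ciliated medians in the vehicle range and cytokine medians of -0.82 or less, but secretory medians of -0.39 and -0.29, below the vehicle arrays, and an effect on the type 2-like cells was not tested.

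Amiodarone replicate 1 lay apart from replicates 2 and 3 in surfactant and airway genes, for example KRT14 (-3.08 against 0.46 and 0.55) and CHGA (1.42 against 4.78 and 4.77). Scan date may account for this and cannot be told apart from a difference between cultures, because it is the only amiodarone array on its date: 2 arrays of 1 group and 1 date lay up to 55.19 apart on the first principal component, less than the 79.18 between the closest amiodarone arrays of different dates. A GNE7915 array in this group was looked for at the 9 genes called with GNE7915. At 5 of them every amiodarone array lay on the vehicle side of the GNE7915 arrays by more than their range. These genes were called in a fit whose spread includes the amiodarone arrays, which favours genes at which those arrays agree. The test therefore cannot exclude a GNE7915 array, and a vehicle array was not tested. A first test, a score over 100 genes that ran from 0.129 to 0.773 in amiodarone arrays (1 at or above 0.5) against at most 0.035 in vehicle and at least 0.93 in GNE7915 arrays, had settled nothing, and the test on called genes was put in its place after the values were seen.

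CPT1A and ECH1 both serve the oxidation of fatty acids in mitochondria, and a lower expression of this pathway with GNE7915 is a hypothesis. Within date 3, where scan date does not part the groups, the falls were -3.93 for CPT1A and -1.24 for ECH1. The ratios of these to the pooled falls (1.06 or more) do not test scan date further. Both genes were picked for passing in a fit that includes these arrays, which favours ratios near 1. The adjusted p of the lists below were taken over the added lists only, not over the lists fixed beforehand. They are therefore more lenient than the adjusted p of the fixed lists and cannot be set beside them. A list of 17 other genes of fatty acid oxidation, written after their values had been seen, had a median of -0.21 (adjusted p = 0.00143; adjusted p = 0.135 with an estimated correlation), with 3 lower adjusted over the list alone, and SLC25A20 gave -1.07, ACAA2 -1.01 and ACADS -0.82; with amiodarone it had 0.03 (adjusted p = 0.871). PPAR target genes, which could fall together with these, had an adjusted p of 0.145 over 20 measured genes, whereas a narrower first list of 15 measured genes, to which 7 genes were later added, had given 0.0073 (0.0677 with an estimated correlation). A change of the class therefore stays open, also between the drugs, where both lists were higher with amiodarone (each adjusted p = 0.0035; 0.0947 with an estimated correlation), as was the narrower PPAR list (0.00162; 0.0303).

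Splits of the 6 arrays into 3 and 3 are 10 for each comparison with the real one, too few for a share under 0.05. For GNE7915 against vehicle the real split called 9 genes and the highest other 1 (1 of 10 splits as large), and it put 11 lists past the threshold against a highest other of 13 (2 of 10). The 3 other splits that part all 3 same-numbered pairs called 0 genes in limma (349, 463 and 720 at an unadjusted p under 0.05) and put 7, 10 and 1 lists past the threshold. For amiodarone against vehicle the real split called 1 gene and the highest other 0 (1 of 10), and 11 lists against 13 (5 of 10). The split that follows scan date, with vehicle replicate 1 and amiodarone replicates 2 and 3 on one side, put as many lists past the threshold, 11, as the real one; with scan date as a block 12 passed, 7 of them shared. Between amiodarone and GNE7915 all 10 splits called 0 genes in limma (the real one had 3064 at an unadjusted p under 0.05, and the one that follows scan date 3171), and the lists were 9 against a highest other of 14 (2 of 10). Of 100 regroupings of the 9 arrays, the real one included, 4 gave as many shared calls as the 1 of TREM1, the highest other being 1. This share is under 0.05, but it rests on 1 gene and on 100 of 840 possible regroupings. The test also treats the arrays as exchangeable, although same-numbered vehicle and GNE7915 arrays deviated together and the scan dates are unbalanced. Chance is therefore not excluded. With either block 0 genes were shared in limma, as the SE was larger and the residual degrees of freedom fewer (4 and 3 against 6). With scan date as a block the fold of TREM1 went from -1.60 (SE 0.11) to -1.60 (SE 0.15) with GNE7915 and, on replicate 1 alone, from -1.57 (SE 0.11) to -1.59 (SE 0.18) with amiodarone. The replicate block is balanced and cannot move a fold (SE 0.12 with both drugs).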
